A study of Mus musculus with 34 samples.

How the data were processed

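The labels describe 34 ChIP-seq samples of Beta-TC6 cells, of which 28 are immunoprecipitated samples in 10 groups and 6 are inputs. Each group had 3 samples, except the SIN3A groups with 2. The labels do not say that the samples of a group came from separate cultures. Library preparation used NEBNext Ultra II for ChIP, per the labels. The tools named in the submitters' processing notes include Bowtie2 and HOMER, with the genome build mm10 and without versions or roles, so the aligner settings are not given in the sources used here. The antibody label of the PDX1 samples with IL-1β, in wild-type and knockout cells, names p65, while their titles name PDX1, and the titles were followed.

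The values used are 10 peak lists made by the authors, 1 per group. Per the file headers, each was called with HOMER findPeaks in its factor style from 1 immunoprecipitated and 1 input tag collection, with a false discovery rate of 0.001, at least 4-fold over input at a p-value of 0.0001, at least 4-fold over the local 10 kb, a fragment length of 100 bp and at most 2-fold clonal tags. The p65 and PDX1 lists of the same condition used the same input, per the file headers. The headers do not say whether replicates were pooled. The signal of a peak is the authors' tag count, normalised by them to 10 M tags per the file headers. The peak score is the authors' HOMER position-adjusted tag count, as deposited. The fold over input is the authors' ratio of immunoprecipitated tags to input tags after scaling to depth, as deposited. In the comparisons these values served only to describe and rank peaks within a list. Among the tests, only those of peak window and of mixed p65 DNA set tag counts and thresholds of different lists against each other. They assume that the normalised counts are on the same scale. Elsewhere tag counts, thresholds and percents of tags inside peaks of different lists are given side by side as description only, and no difference in signal is read from them.

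No replicate value is in the lists, so no test between conditions was made. Before the data were examined it was decided that a comparison would be the share of peaks of a first list that overlap a peak of a second list by at least 1 bp, with a Wilson 95% interval, which covers counting error only and not the spread between replicates. Chance overlap was measured by shifting the second list 10 times, in steps of 20 kb up to 100 kb to each side. The 12 gene lists and the alternatives with a reciprocal overlap of 50%, centres within 100 bp, at least 8-fold over input, equal list lengths and gene distances were also fixed before the data were examined. Counting peaks within 500 bp as shared, and comparing equally long top lists for reference, were chosen after the data had been seen, as was weighting bins by their number of SIN3A peaks at PDX1 peaks. Bins of tag count or score are 4 equal parts of a list.

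The written design assigned each peak to the nearest transcription start. The gene table, of the same assembly as mm10, gives no strand, so each peak was instead assigned to the nearest of 21887 protein-coding gene bodies of the nuclear chromosomes within 50 kb. Of 236 listed genes 235 were matched, Cxcl11 having no protein-coding entry, and Ero1lb is listed as Ero1b. For each gene list and group, the number of genes with a peak was set against 10000 random lists of as many genes matched on the decile of the length of genome nearest to each gene, giving 120 counts, without correction for their number. Genes sharing a peak between lists were counted among members with a peak and matched on the decile of the highest tag count. They were not matched on the number of peaks per gene, any of which could be the shared one, or on having a peak in the second list. Motifs were not analysed here, since no genome sequence was used. The other 2 alternatives planned for replicates, leaving a replicate out and a replicate block, were not run.

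Counts of the 12 gene lists not given elsewhere, with the central 95% of random lists in brackets, follow. For p65 in wild-type control cells they were 3 cytokine genes (0 to 3), 3 core clock (0 to 6), 8 insulin and secretion (1 to 7), 4 other islet endocrine (0 to 3), 4 disallowed (0 to 4), 2 endoplasmic reticulum stress and apoptosis (0 to 4), 1 immediate early (0 to 3), 0 SIN3 and HDAC complex (0 to 4), 4 neuronal (0 to 5) and 3 genes of other lineages (0 to 4). For p65 in knockout cells with IL-1β they were 7 other islet endocrine (2 to 8), 6 disallowed (2 to 9), 10 stress and apoptosis (2 to 9), 8 SIN3 and HDAC complex (2 to 9), 9 neuronal (3 to 10) and 6 of other lineages (2 to 9). For PDX1 in wild-type cells, without and with IL-1β, they were 8 and 9 cytokine genes (3 to 10 in both), 9 and 10 disallowed (4 to 10 in both), 8 and 9 stress and apoptosis (3 to 10 in both), 9 and 8 immediate early (3 to 10 and 3 to 9), 7 and 10 SIN3 and HDAC complex (4 to 11 in both), 12 and 11 neuronal (6 to 12 in both) and 5 and 4 of other lineages (3 to 11 and 3 to 10). With IL-1β, 20 β-cell transcription factor genes (8 to 16), 22 insulin and secretion genes (10 to 19) and 10 other islet endocrine genes (3 to 9) had a wild-type PDX1 peak. For PDX1 in knockout cells, without and with IL-1β, they were 8 and 9 NF-κB targets (1 to 9 and 1 to 8), 1 and 2 cytokines (0 to 5 in both), 6 and 5 core clock (2 to 9 and 2 to 8), 7 and 6 other islet endocrine (0 to 5 in both), 5 and 2 disallowed (0 to 6 in both), 4 and 4 stress and apoptosis (0 to 5 in both), 4 and 4 immediate early (0 to 5 in both), 1 and 2 SIN3 and HDAC complex (0 to 6 and 0 to 5), 7 and 5 neuronal (1 to 7 in both) and 0 and 2 of other lineages (0 to 5 in both). For SIN3A, 9 disallowed genes had a peak with control siRNA (3 to 11). With Pdx1 siRNA the counts were 24 NF-κB targets (10 to 21), 1 cytokine (5 to 13), 20 core clock (7 to 17), 17 β-cell transcription factors (7 to 16), 22 insulin and secretion (10 to 21), 4 other islet endocrine (3 to 10), 7 disallowed (4 to 11), 14 stress and apoptosis (4 to 12), 14 immediate early (4 to 11), 15 SIN3 and HDAC complex (4 to 12), 12 neuronal (5 to 12) and 2 of other lineages (5 to 14).

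Genes were named by a rule, up to 4 members of each fixed list per class of peaks by highest tag count and the 5 genes nearest the highest-scored peaks of each class. Nfkbia, Tnfaip3, Nfkb1, Birc3, Ccl2, Nos2, Ins1, Ins2, Pdx1, Mafa, Nkx6-1, Per1, Per2, Cry1, Nr1d1 and Dbp were to be named always. Other genes are named as members of a fixed list that differ between lists or share a peak, and some of these were chosen after the values had been seen. Dbp had no peak in any list.

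The procedure was tested on simulated data. With 16000 simulated peaks and a planted share of 40%, 40.2% were found, and 0.358% after shifting. With no effect planted, the difference within bins was 0.372 percentage points where the crude difference was 16.0, and a planted difference of 10 points came back as 9.54. The simulated shares were constant within each bin, so this cannot show that bins remove differences in peak strength inside a bin. Random gene lists had a median percentile of 44.6, and 3.5% of them lay above the upper limit of the central 95%, more than that limit intends, so a count just above its range is weak evidence. The work used Python 3.11.15, bedtools 2.31.1, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, with random seed 20.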

Results

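Chromatin immunoprecipitation with sequencing (ChIP-seq), which recovers the DNA bound by a chosen protein, was applied to 3 proteins in Beta-TC6 cells, a mouse insulin-producing β-cell line. The proteins were p65 (RELA), the transactivating subunit of NF-κB, PDX1, the homeodomain factor that maintains β-cell identity, and SIN3A, the scaffold of a histone deacetylase corepressor complex. Wild-type and Bmal1 knockout cells, which lack an activator of the core circadian clock, were compared with and without the inflammatory cytokine IL-1β for p65 and PDX1, with 3 immunoprecipitated samples in each of these 8 groups. SIN3A was examined in wild-type cells given a control or a Pdx1 siRNA, with 2 samples per group. All cells had been synchronised with a 1 h pulse of 10 µM forskolin, and the IL-1β dose and time are not given in the sources used here. Together with 6 input samples the series holds 34 samples, but the files used here hold 1 peak list per group and no value per replicate. No comparison could therefore be set against the spread between replicates, and the intervals given are Wilson 95% intervals of a share of peaks, which cover counting error only. The titles question how NF-κB and circadian enhancers relate to β-cell function. The lists carry no expression values, so neither the loss of Bmal1 nor the depletion of Pdx1 could be checked in them.

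Sequencing depth was similar among the p65 and PDX1 lists, from 53.5 to 63.9 M tags, and lower for SIN3A, at 31.0 M with control siRNA and 35.0 M with Pdx1 siRNA. The number of peaks differed far more than the depth. In wild-type cells p65 had 3157 peaks under control conditions and 31389 with IL-1β, and in the knockout 173 and 16162. PDX1 had 40028 and 38930 peaks in wild-type cells and 8339 and 8095 in the knockout, again without and with IL-1β. Of the 30971 putative peaks behind the 173, 95.5% were removed against input, compared with 81.8% for wild-type control p65. With IL-1β the p65 values were 52.02% in the knockout and 56.6% in wild-type cells. For PDX1 they were 80.5% and 78.1% in the knockout and 59.7% and 60.04% in wild-type cells. Tag thresholds were 35 and 21 for knockout p65 and 34 and 32 for knockout PDX1. In wild-type cells they were 20 and 19 for p65 and 20 and 22 for PDX1. SIN3A had 13109 peaks with control siRNA and 14653 with Pdx1 siRNA. SIN3A peaks lay near genes, with 68.2% and 65.5% of them within 1 kb of an end of a protein-coding gene, against 10.8% and 10.4% for p65 and 3.82% and 3.34% for PDX1 in wild-type cells.

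**Figure D1:**
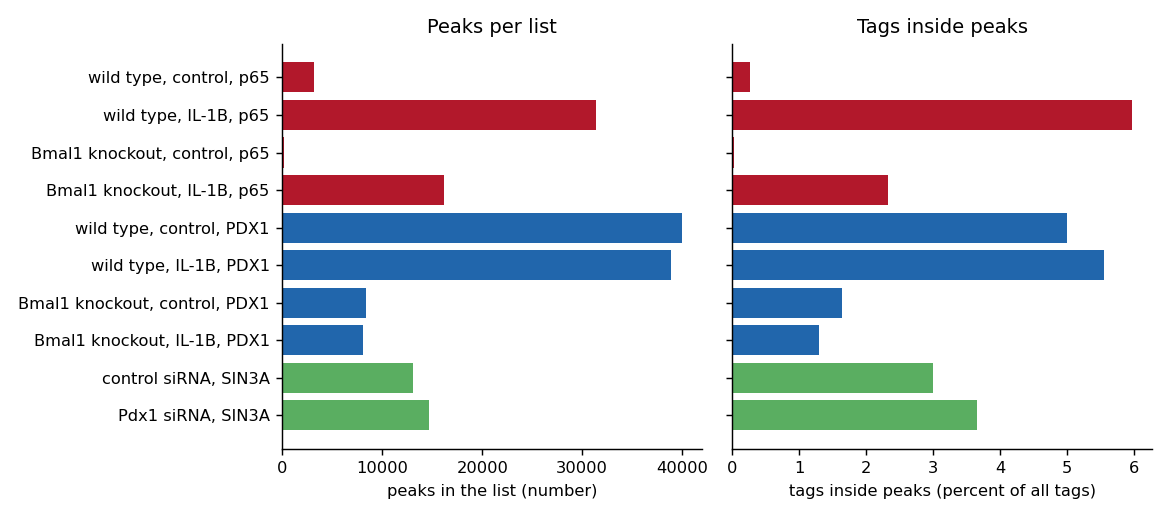
Horizontal bars give, for each of the 10 lists, the number of peaks and the percent of tags that lie inside peaks, with p65 in red, PDX1 in blue and SIN3A in green. The percent of tags inside p65 peaks was 0.27 without and 5.98 with IL-1β in wild-type cells and 0.03 and 2.33 in the knockout, and the percent inside PDX1 peaks was 5 and 5.55 in wild-type cells and 1.64 and 1.29 in the knockout.

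With IL-1β, p65 in wild-type cells was found at the regulators of its own pathway and at β-cell genes alike. The random gene lists, here and below, came from all protein-coding genes and were not matched on expression. A count above them therefore does not by itself show targeting of a gene class. Of 32 NF-κB target genes 29 had a p65 peak, while 9 to 20 did so in the central 95% of random gene lists of the same size and gene spacing, and none of 10000 random lists reached 29. The highest-scored peak of the list lay inside Nfkbia, which encodes the inhibitor IκBα (mm10 chromosome 12, 55491841 to 55492047, 509.8 tags per 10 M sequenced tags), and the next beside Tnfaip3, which encodes the deubiquitinase A20 that restrains NF-κB (chromosome 10, 19015321 to 19015527, 811 tags). Peaks also lay at 15 of 19 cytokine and chemokine genes (random lists 4 to 11), among them Tnf (319.8 tags), Cxcl1 (117 tags) and the monocyte attractant Ccl2 (63.9 tags), and at Nos2, the inducible nitric oxide synthase (214 tags, 33567 bp outside the gene). Of 22 β-cell transcription factor genes 21 had a p65 peak (random lists 9 to 17), Insm1 being the exception.

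Metabolic and secretory genes of the β-cell were among these p65 sites. Of 30 insulin and secretion genes 23 had a peak (random lists 11 to 20), including Abcc8, the sulfonylurea receptor subunit of the ATP-sensitive potassium channel (276 tags), and Cpe, which trims prohormones (217 tags). Pdx1 itself had 4 peaks, the highest 22744 bp from the gene (97.3 tags), and Mafa, an insulin gene activator, had 1 peak 128 bp from the gene (57.9 tags). The p65 peaks assigned to the insulin genes were weak, with 16.8 tags for Ins1 and 3.92 tags for Ins2. The peak assigned to Ins2 lay outside the gene, at 142692585 to 142692791 on chromosome 7, where Ins2 spans 142678656 to 142679726. Core clock genes had peaks in 17 of 23 cases (random lists 8 to 16), the highest at Nr1d2, a nuclear receptor repressor of the clock (164 tags), Per1, a period gene (131 tags), and Arntl, the gene of BMAL1 (129 tags). Immediate early genes had peaks in 14 of 15 cases (random lists 3 to 10, Junb with 539 tags), genes of endoplasmic reticulum stress and apoptosis in 14 of 16 (random lists 4 to 11), SIN3 and HDAC complex genes in 13 of 16 (random lists 4 to 11) and neuronal genes in 14 of 16 (random lists 6 to 13). Within the random range were the 8 of 12 genes of other islet endocrine cells (3 to 9), the 10 of 14 disallowed or dedifferentiation genes (4 to 11), and the 7 of 20 markers of other lineages (4 to 12), although Pecam1, an endothelial adhesion molecule, carried 433 tags and Myod1, a muscle regulator, 182 tags.

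Without IL-1β the wild-type p65 list was far shorter, and in it the feedback genes already appeared. NF-κB target genes had a control peak in 14 of 32 cases (random lists 0 to 6), and each of the 14 shared a peak between both conditions. Nfkbia (45.6 tags) and Tnfaip3 (34.2 tags) ranked 14 and 38 in the control list. Of the β-cell transcription factor genes 4 of 22 had a control peak (random lists 0 to 6), and none of the 21 with a peak under IL-1β shared it with the control list (0 against 1 to 7 in random lists matched on tag count). Insulin and secretion genes had a control peak in 8 of 30 cases, just above the random range (1 to 7). Of the 23 with a peak under IL-1β 7 shared it, at the upper limit of the range (1 to 7). Disallowed genes did so in 4 of 10 cases (0 to 3). Of the IL-1β p65 peaks shared with the control list 70.2% overlapped an IL-1β PDX1 peak. Background at strongly recovered PDX1 sites stays open for control p65 peaks. Only 5.07% of the IL-1β peaks (4.83 to 5.32%, 1592 of 31389) overlapped a control peak, against 0.0838% after one list was shifted by 20 to 100 kb. At gene level, 8301 genes had a p65 peak with IL-1β and not without it, and 211 the reverse. Limiting both lists to 3157 peaks gave 15.2%, and peaks of at least 8-fold over input gave 2.49%.

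In Bmal1 knockout cells p65 had peaks at feedback genes of its pathway without and with IL-1β. The control list was very short, and its 173 peaks included Nfkbia (39.7 tags), Tnfaip3 (29.4 tags), Nfkb2, Relb and Nfkbib, so that 5 of 32 NF-κB target genes had a peak (random lists 0 to 1). Among the other lists it held a peak only at Ldha, encoding lactate dehydrogenase A, and Junb. With IL-1β 28 of 32 NF-κB target genes had a peak (random lists 5 to 15), again with Nfkbia (197 tags) and Tnfaip3 (265 tags) as the highest-scored pair, and Tnf (205 tags) ranked 4 in the list. The counts were 11 of 19 for cytokines (random lists 2 to 9), 17 of 22 for β-cell transcription factors (5 to 13), 21 of 30 for insulin and secretion (7 to 16), 14 of 15 for immediate early genes (1 to 8) and 12 of 23 for the core clock (5 to 13). Only 0.724% of the knockout IL-1β peaks (0.604 to 0.867%, 117 of 16162) overlapped a knockout control peak, while 67.6% of the control peaks (117 of 173) were found again. The share rested on the short control list, being 21.4% when both lists held 173 peaks and 0 under a reciprocal overlap of 50%, which peak widths of 479 and 231 bp do not allow.

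Most strong p65 sites of IL-1β-treated wild-type cells were present in the knockout. A shared peak was found for 27 of the 29 NF-κB target genes with a wild-type peak (random lists matched on tag count 24 to 28). Tnfaip2 and the anti-apoptotic gene Bcl2l1 had a wild-type peak only, both weak (12.1 and 7.47 tags), and Stat5a a knockout peak only. The genes of the chemokines Cxcl5, Cxcl9 and Cxcl16 and of the cytokine Il1a had a peak in wild-type cells alone, with at most 12.1 tags. Abcc8 (276 tags in wild-type cells, 88.8 in the knockout list), Pdx1 (97.3 and 47.7) and Mafa (57.9 and 25.8) were found in both, and Ins2, the incretin receptor genes Glp1r and Gipr, and the transcription factor genes Nkx6-1, Pax4 and Foxa1 were among those found only in wild-type cells.

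The number of clock genes sharing a p65 peak between genotypes was at the low edge of its random range. Of 17 core clock genes with a wild-type peak 10 shared one with the knockout, where matched random lists gave 10 to 15 (percentile 3.82, the lowest of the 12 lists). Npas2, Per2, Per3, Nr1d1, Tef and Csnk1e had a p65 peak only in wild-type cells, the highest being Nr1d1 with 31.4 tags and Per3 with 28.6, whereas Per1, Nr1d2, Cry2 and Arntl had a shared peak. Cry1, a repressor of the clock, and Dbp, a clock output gene, had no p65 peak in either list. Of all wild-type IL-1β peaks 40.7% (40.2 to 41.3%, 12781 of 31389) were found in the knockout, against 0.476% after shifting, and 79.1% of the knockout peaks were in the wild-type list. Sharing followed peak strength, with 87.8%, 47.7%, 20.9% and 6.40% from the highest to the lowest of 4 equal bins by wild-type tag count, and 98.9% for the top 5%. At gene level 6559 genes had a peak in both, 3498 in wild-type cells only and 611 in the knockout only. With lists of equal length the share was 66.8%.

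**Figure D2:**
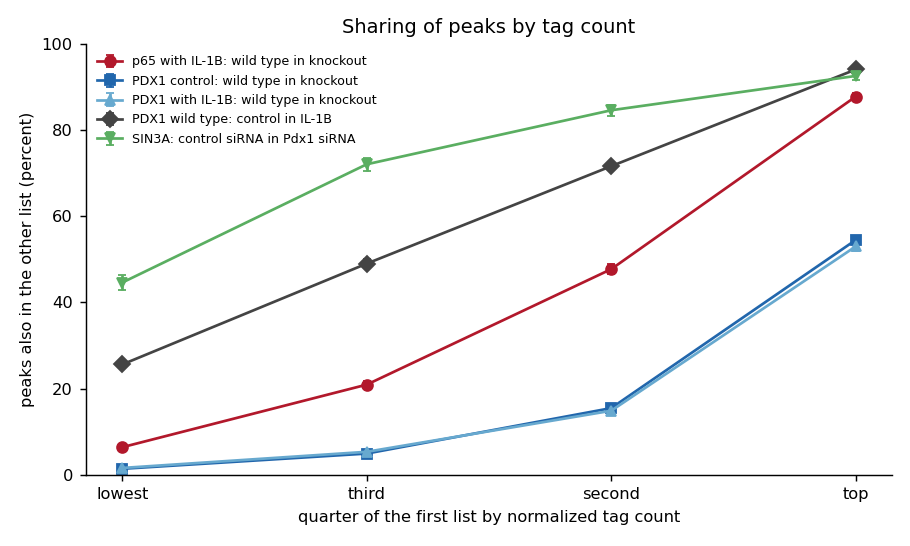
Each line gives the percent of peaks of a first list that are also in a second list (vertical axis) for 4 equal bins of the first list by normalised tag count (horizontal axis), with error bars of Wilson 95% intervals over peaks. For p65 in wild-type against knockout cells with IL-1β the share runs from 87.8% in the top bin to 6.40% in the lowest, for PDX1 under control conditions from 54.5% to 1.39%, and for SIN3A with control against Pdx1 siRNA from 92.6% to 44.6%.

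PDX1 occupied β-cell genes with and without IL-1β. In wild-type control cells it had a peak at 21 of 22 β-cell transcription factor genes (random lists 8 to 16), at 21 of 30 insulin and secretion genes (10 to 19) and at 10 of 12 genes of other islet endocrine cells (3 to 9). Slc30a8, the zinc transporter of insulin granules (123 tags), Cpe (114 tags), Rfx3, a regulator of ciliated and endocrine cells (108 tags), Sst, encoding somatostatin (106.5 tags), and Hk1, a hexokinase normally low in β-cells (112 tags), carried some of the highest counts. Its own gene had a peak 5737 bp away (chromosome 5, 147264257 to 147264463, 73.8 tags), Nkx6-1 one at 13784 bp (90.1 tags), and Ins2 one 234 bp from the gene (chromosome 7, 142679857 to 142680063, 89.9 tags). Each of the 21 insulin and secretion genes shared a peak with the IL-1β list (19 to 21 in random lists matched on tag count). Of the 21 β-cell transcription factor genes 19 did so (17 to 21), so both counts lay within the random range.

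Some inflammatory genes were among the many genes with a PDX1 peak only with or only without IL-1β in wild-type cells. Of all genes, 1470 had one only with IL-1β, 1580 only without it and 7594 in both. NF-κB target genes had a PDX1 peak in 14 of 32 cases without and 18 with IL-1β (random lists 8 to 18 in both). Nfkbie, Nfkbid, Rel, Bcl2l1 and Nos2 had a peak only with IL-1β and Sod2, encoding mitochondrial superoxide dismutase, only without it, while among cytokine genes, 8 of 19 without and 9 with IL-1β (3 to 10 in both), Ccl2 and Cxcl2 had a PDX1 peak only with IL-1β and Cxcl10 only without it. Per1, Per2 and Npas2 had a PDX1 peak only without IL-1β and Nr1d1, Nr1d2, Hlf and Csnk1d only with it, all with at most 13.4 tags, and the core clock counts were 14 and 15 of 23 (random lists 7 to 16 and 8 to 16). Of the control peaks 60.1% (59.6 to 60.6%, 24051 of 40028) were in the IL-1β list, against 0.929% after shifting, with 94.1% in the top of 4 bins by tag count and 25.6% in the lowest. Control-only peaks numbered 15977 and IL-1β-only peaks 14879. Among peaks assigned to a gene, the highest-scored of both classes lay at Rfx6, a transcription factor of islet development. The control-only class also held a mitochondrial peak, at 9721 to 9927, rank 5 of its list. Few control-only peaks were near misses, as 15192 of them had no IL-1β peak within 500 bp. Raising the bar to 8-fold over input gave a share of 40.4%.

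In knockout cells PDX1 kept 58.8% of its control peaks with IL-1β (57.8 to 59.9%, 4906 of 8339), against 0.489% after shifting. Wild-type lists limited to the 8339 strongest peaks shared 83.4% (82.6 to 84.2%), so the similar shares of the full lists, 60.1% and 58.8%, do not show equal retention in both genotypes. It lay at 13 of 22 β-cell transcription factor genes without and 14 with IL-1β (random lists 2 to 9 in both), with Isl1 among those listed only with IL-1β and Pax4 only without. Insulin and secretion genes had a peak in 19 and 16 of 30 cases (random lists 3 to 10 in both), and Ins2 and the prohormone convertase gene Pcsk1 were among those that had none with IL-1β. The knockout control peak at Ins2 (60.3 tags) was 4.85-fold over input, near the authors' 4-fold limit. Irf1, an interferon response factor, Tnf, Jun and the apoptosis gene Bbc3 had a PDX1 peak only with IL-1β. Of all genes, 928 had a knockout PDX1 peak only with IL-1β and 1010 only without it. In wild-type cells Irf1, Jun and Bbc3 shared a PDX1 peak between both conditions, and Tnf had none. At 8-fold over input in both lists the share was 37.0%.

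**Figure D3:**
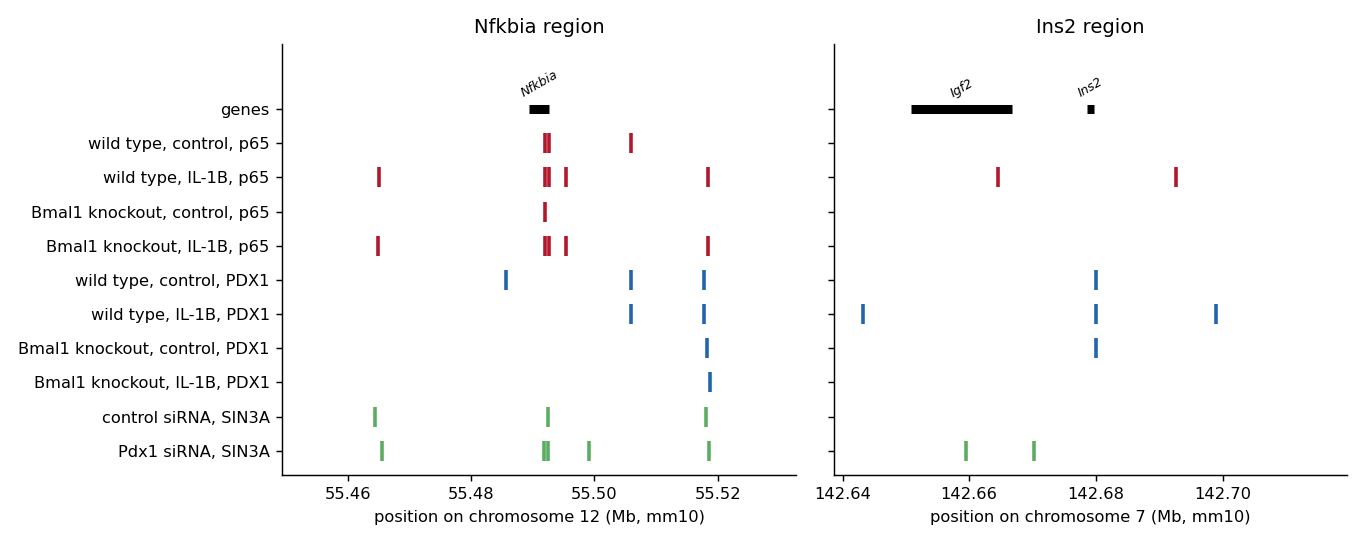
Horizontal axes give mm10 coordinates 40 kb to each side of Nfkbia on chromosome 12 and of Ins2 on chromosome 7, with ticks for the peaks of the 10 lists and black bars for gene bodies. The p65 lists share the peak inside Nfkbia in all 4 conditions, and the PDX1 peak beside Ins2 is in 3 of the 4 PDX1 lists, being absent from the knockout list with IL-1β.

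PDX1 peaks were fewer in Bmal1 knockout cells, and the genes that held none there included regulators of mature β-cells. Without IL-1β, Mafa, Neurod1, Isl1, Foxa1 and Hnf4a were among the genes with a PDX1 peak in wild-type cells only, as did Glp1r and Ucn3, encoding the β-cell maturation marker urocortin 3, while Pdx1 (39.3 tags), Nkx6-1 (63.2), Ins1 (42.4), Ins2 (60.3) and Slc30a8 (127) had one in both. Among the core clock genes Npas2, Per1, Per2, Per3, Cry1, Rorb, Bhlhe40 and Bhlhe41 had a wild-type peak only and Hlf a knockout peak only, and 1 of the 8 cytokine genes with a wild-type peak shared it with the knockout (0 to 3 in matched random lists). Set against random genes of the same tag count, 13 of 21 β-cell transcription factor genes shared a peak (11 to 17), 19 of 21 insulin and secretion genes (14 to 20) and 4 of 14 core clock genes (3 to 9). SIN3 and HDAC complex genes shared 1 of 7 (1 to 5, percentile 1.63), the one being Arid4b. None of the 5 markers of other lineages with a wild-type peak shared it (0 to 3).

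Nearly all knockout PDX1 peaks were in the wild-type list (91.6%, 90.9 to 92.1%, against 1.61% after shifting), but 19.1% of the wild-type control peaks were found in the knockout (18.7 to 19.5%, 7636 of 40028), and 18.7% with IL-1β (18.3 to 19.1%, 7280 of 38930, against 0.312% after shifting). By tag count the control share was 54.5%, 15.5%, 4.93% and 1.39% from the highest to the lowest bin and 90.7% in the top 5%. Genes with a PDX1 peak in both genotypes under control conditions numbered 3503, with 5671 in wild-type cells only and 100 in the knockout only. The authors' peak widths differed, 207 bp in wild-type and 472 bp in knockout control cells, and with 8339 peaks in both lists the share was 60.2% (59.2 to 61.3%). The wild-type control and IL-1β PDX1 lists of that length shared 83.4%. The knockout control and IL-1β lists shared 58.8% (57.8 to 59.9%). Under control conditions the share between genotypes was thus no lower than that between the knockout lists. With IL-1β and lists limited to 8095 peaks, the share between genotypes was 58.5% (57.4 to 59.6%). The knockout lists of that length shared 59.96%, slightly more, with overlapping intervals.

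Under IL-1β, p65 and PDX1 met at insulin and secretion genes just above the random range and at NF-κB target genes just below it. The random lists were matched on p65 tag count, not on the number of p65 peaks per gene or on having a PDX1 peak. Genes with many p65 peaks could thus meet PDX1 more easily. A p65 peak overlapping a PDX1 peak was found at 18 of the 23 insulin and secretion genes with a p65 peak (8 to 17 in random lists matched on p65 tag count), among them Abcc8, Cpe, Slc30a8 and Ins1, and at 7 of 8 genes of other islet endocrine cells (1 to 6). β-cell transcription factor genes had such a peak in 15 of 21 cases (7 to 16), Pdx1 and Nkx6-1 included and Mafa not. NF-κB target genes had one in 12 of 29 cases (13 to 23), with Tnfaip3, Nfkb1 and Nos2 among them and Nfkbia and Birc3, encoding an inhibitor of apoptosis, outside. For immediate early genes the count was 3 of 14 (5 to 12), at Fos, Jun and Klf4, and for core clock genes 5 of 17 (5 to 13), at Arntl, Cry2, Rora, Nfil3 and Bhlhe40. Of all wild-type IL-1β p65 peaks 33.8% (33.3 to 34.3%, 10612 of 31389) overlapped a PDX1 peak of the same cells, against 0.920% after shifting, and 22.0% did so at 8-fold over input. At gene level 6977 genes had a peak of both factors.

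PDX1 peaks present only with IL-1β lay at p65 peaks more often than those present only without it. In wild-type cells 22.5% (21.8 to 23.2%) of the IL-1β-only PDX1 peaks overlapped an IL-1β p65 peak, against 4.43% (4.12 to 4.76%) of the control-only PDX1 peaks and 30.2% of those in both lists. In the knockout the shares were 39.5% (37.9 to 41.3%), 10.3% (9.31 to 11.3%) and 46.6%. Within 4 bins of PDX1 tag count, wild-type IL-1β-only peaks instead exceeded those in both lists, by 9.99 points (8.82 to 11.2). The IL-1β PDX1 and p65 lists of a genotype were called against the same input, and with the p65 list of the other genotype, called against another input, the IL-1β-only and control-only shares were 12.0% and 3.25% for wild-type PDX1 peaks and 43.1% and 27.5% for knockout PDX1 peaks. Nos2, Ccl2 and Cxcl2 are examples of genes with p65 peaks under IL-1β and a PDX1 peak listed only then.

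**Figure D4:**
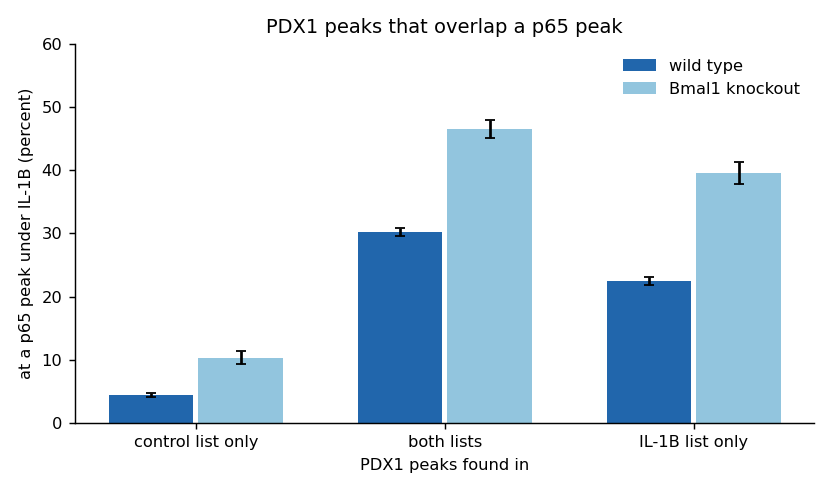
Bars give the percent of PDX1 peaks that overlap an IL-1β p65 peak of the same genotype, for PDX1 peaks in the control list only, in both lists and in the IL-1β list only, with error bars of Wilson 95% intervals over peaks. In wild-type cells the bars stand at 4.43%, 30.2% and 22.5%, and in the knockout at 10.3%, 46.6% and 39.5%. The peaks were not matched on tag count.

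Whether p65 sites that carry PDX1 were found more often in the knockout depended on the use of score bins or of a higher fold over input. Wild-type p65 peaks with a PDX1 peak, such as those at Abcc8, were in the knockout p65 list in 44.6% of cases and those without in 38.7%, a difference of 5.91 percentage points (Newcombe 95% interval 4.75 to 7.06). Within 4 equal bins of p65 peak score the difference was −2.21 points (−3.09 to −1.33), with 87.8% and 88.1% in the highest bin and 18.5% and 22.0% in the bin above the lowest. At 8-fold over input it was −0.174 points (−1.86 to 1.54).

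SIN3A lay mostly near gene ends, and genes of the clock and of its own corepressor complex were among its sites. With control siRNA the highest-scored peak was in Trmt61a, encoding a tRNA methyltransferase subunit (chromosome 12, 111678048 to 111678272, 164 tags). SIN3A had a peak at 19 of 23 core clock genes (random lists 7 to 16), among them Nr1d1 (75.7 tags), Cry1 (54.8), Per1 (36.1) and Per2 (30.3), and at 15 of 16 SIN3 and HDAC complex genes (4 to 12), with Arid4a highest at 93.4 tags. It was found at 22 of 32 NF-κB target genes (10 to 21), 17 of 22 β-cell transcription factor genes (6 to 16), 22 of 30 insulin and secretion genes (10 to 20), 14 of 16 endoplasmic reticulum stress and apoptosis genes (4 to 11), 12 of 15 immediate early genes (3 to 11) and 13 of 16 neuronal genes (4 to 12). None of 19 cytokine genes (5 to 13), 1 of 20 markers of other lineages (5 to 14) and 3 of 12 genes of other islet endocrine cells (3 to 9) had a SIN3A peak, and Ins1, Ins2, Pdx1, Birc3, Ccl2 and Nos2 had none.

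With Pdx1 siRNA most of these sites stayed in the list. Nr1d1 (80.1 tags), Cry1 (76.1), Per1 (43.5) and Per2 (45.2) had a SIN3A peak again, and 18 of the 19 core clock genes shared a peak (14 to 19 in matched random lists). Nkx2-2 and Pax6, both islet transcription factor genes, Slc2a2, the glucose transporter gene, Sin3a itself, Hk1, Smad3, Cd81 and Gria2 were among the genes with a SIN3A peak only with control siRNA. Pax4, Foxa1, G6pc2, Stx1a, Cd40, Stat5a, Nfil3, Jun, Ier3, Hdac1, Cxcl10, Irx2, Gast, Stmn2 and Pecam1 had one only with Pdx1 siRNA. Of the control siRNA peaks 73.5% (72.7 to 74.2%, 9632 of 13109) were found again, against 0.744% after shifting, while 3477 were not and 5021 were new. At gene level 9682 genes had a SIN3A peak in both, 714 only with control siRNA and 1267 only with Pdx1 siRNA. Some of the unshared peaks lay close to a peak of the other list, as 86.3% of all control siRNA peaks overlapped or lay within 500 bp of one, while 1798 did not.

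SIN3A and PDX1 peaks overlapped seldom, and where they did β-cell genes stood out. An overlapping peak was found at 6 of the 17 β-cell transcription factor genes with a SIN3A peak (0 to 4 in random lists matched on SIN3A tag count), namely Nkx6-1, Neurod1, Hnf4a, Glis3, Myt1 and St18, and at 7 of 22 insulin and secretion genes (0 to 4), among them Slc2a2, Abcc8, Cacna1c, Cacna1d and Glp1r. None of 14 endoplasmic reticulum stress and apoptosis genes and none of 12 immediate early genes had an overlapping peak (0 to 3 for both). The random lists were not matched on having a PDX1 peak. All of the 17 transcription factor genes but Insm1 had one, against 5802 of all 10396 genes with a SIN3A peak. More overlap at these genes could follow from that alone. In all, 6.84% of the control siRNA SIN3A peaks (6.42 to 7.28%, 896 of 13109) overlapped a wild-type control PDX1 peak, against 0.785% after shifting. The share was 3.52% under a reciprocal overlap of 50%, 2.76% at 8-fold over input and 13.9% within 500 bp, and the PDX1 list came from cells without siRNA.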

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

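The results weighed in this part were picked from the tables after they were seen, while the conditions of their tests on the shorter knockout lists were written before those tests were run and none of these was added afterwards.

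The knockout lists were shorter than the wild-type lists for PDX1 and for p65. A wider peak window of the knockout list could remove weak PDX1 peaks, since 472 against 207 bp is a ratio of 2.28, but only 55.9% (54.8 to 57.0%, 4613 of 8253) of the wild-type PDX1 peaks strong enough to survive that dilution were in the knockout list, short of the 90% set for this cause and above the 50% set against it. For p65 the ratio was 1.12 and the share 45.8% (45.2 to 46.4%, 12165 of 26570), which argues against the window as the cause there. Weaker recovery at the same sites might also shorten a list. The knockout lists held 90.7% (89.4 to 91.9%, 1816 of 2002) of the top 5% of wild-type PDX1 peaks and 98.9% (98.2 to 99.3%, 1552 of 1570) of the top 5% of p65 peaks. With 91.6% of the knockout PDX1 peaks in the wild-type list, PDX1 met the written condition of at least 90% and over 80%. The interval of the former, not part of that condition, reaches below 90%. For p65 the condition was not met, as only 79.1% of the knockout peaks were in the wild-type list where over 80% was asked. Such values cannot tell recovery from an effect on binding at weaker sites. An effect of Bmal1 loss on binding, differences between libraries and recovery therefore all stay open, as does the peak window for PDX1. Removal of putative peaks against the input of each list was not tested as a cause and stays open too.

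The percent of tags inside PDX1 peaks differed with IL-1β by 0.55 in wild-type cells and by −0.35 in the knockout, and these opposite directions were not tested because there is no value per replicate. Mitochondrial DNA gave PDX1 peaks in wild-type cells, at 13425 to 13631 (5.72-fold over input, rank 1) and 9721 to 9927 (5.73-fold, rank 5) without IL-1β and at 13415 to 13641 (4.96-fold, rank 1) with it, and these entered the overlaps but not the gene counts, which cover nuclear chromosomes only. Mafa had a p65 peak with IL-1β in both genotypes, 128 bp from the gene in wild-type and 142 bp in knockout cells, while its PDX1 peak was listed in wild-type cells only.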

How the results depend on the processing

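Counting peaks within 500 bp as shared, and the reference of equally long top lists, were chosen only after the results were seen, and the other settings before the data were examined. Values are shares in percent, in the order p65 IL-1β in control (wild type, then knockout), p65 wild type in knockout, PDX1 control in IL-1β (wild type, then knockout), PDX1 wild type in knockout (control, then IL-1β), SIN3A control in Pdx1 siRNA, p65 at PDX1, and SIN3A at PDX1. The main values were 5.07, 0.724, 40.7, 60.1, 58.8, 19.1, 18.7, 73.5, 33.8 and 6.84.

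A reciprocal overlap of 50% gave 4.13, 0, 36.2, 53.6, 57.3, 0, 16.5, 53.1, 25.7 and 3.52. Both values of 0 follow from construction, as peaks of 479 and 231 bp or of 207 and 472 bp cannot cover 50% of each other. For the rest the cause was not tested.

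Centres within 100 bp gave 4.09, 0.588, 35.9, 53.1, 48.8, 16.6, 15.9, 51.8, 25.3 and 3.49, and the cause was not tested.

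At least 8-fold over input gave 2.49, 0.233, 36.4, 40.4, 37.0, 8.71, 10.3, 60.5, 22.0 and 2.76, and the cause was not tested.

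Equal list lengths gave 15.2, 21.4, 66.8, 61.4, 59.96, 60.2, 58.5, 71.7, 31.8 and 4.57. The cause was not tested, though shares were higher among strong peaks, for p65 in the knockout 87.8 in the top bin and 6.40 in the lowest.

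Counting peaks within 500 bp gave 5.72 for wild-type p65 with IL-1β, 42.0 for p65 in the knockout, 62.0 for wild-type PDX1 with IL-1β, 19.5 for control PDX1 in the knockout, 86.3 for SIN3A, 39.0 for p65 at PDX1 and 13.9 for SIN3A at PDX1. A wider reach can only add peaks, by construction.

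The difference in knockout sharing between p65 peaks with and without PDX1, 5.91 points, was 5.27 (4.03 to 6.51) with centres within 100 bp and 7.01 (5.89 to 8.14) within 500 bp, but turned to −0.174 (−1.86 to 1.54) at 8-fold over input and to −2.21 (−3.09 to −1.33) within bins of peak score, and the cause was not tested. The count of NF-κB target genes with a p65 peak, 29 of 32, stayed at 28 to 32 under every setting tried.

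No paired analysis was possible because the lists hold 1 set of peaks per group and no value per replicate. Leaving out a replicate, a replicate block and motif alternatives were not run, the last because no genome sequence was used.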

Other observations

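The tests of p65 antibody, of mixed p65 DNA and of a shared input in the PDX1 lists with IL-1β were written only after the result was seen, as were the count within 500 bp and the weighting of bins for SIN3A, and the other tests before they were run.

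SIN3A with control siRNA met p65 of IL-1β-treated cells at 12.5% of its peaks (11.9 to 13.1%, against 0.902% after shifting). Among p65 peaks with IL-1β, those found only in the knockout lay at SIN3A peaks in 12.9% of cases (11.8 to 14.1%, 437 of 3381), those in both genotypes in 6.80% and those only in wild-type cells in 4.13%. These classes were not matched on distance to gene ends. Within 1 kb of a gene end lay 14.3% of knockout and 10.4% of wild-type p65 peaks with IL-1β, against 68.2% of SIN3A peaks. Whether that accounts for the shares was not tested, and the SIN3A list came from wild-type cells given siRNA. Of 13 SIN3 and HDAC complex genes with a p65 peak in wild-type cells with IL-1β, 8 shared it with the knockout, within the 4 to 10 of matched random lists, and Sin3b, Suds3, Kdm5a, Arid4a and Arid4b had none there. The metabolic gene regulator Mlxipl had p65 peaks in both genotypes (181 and 61.8 tags), as did Ern1, a sensor of endoplasmic reticulum stress (184 and 59.5 tags), and Ddit3, which encodes the stress factor CHOP (93.4 and 52.1 tags).

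PDX1 peaks listed only with IL-1β often lay at p65 peaks in wild-type cells, and the antibody label raises the possibility that the lists could come from p65 antibody, but 27.3% of the wild-type IL-1β PDX1 peaks were in the p65 list and 61.8% in the control PDX1 list (43.8% and 60.6% in the knockout), which argues against it. Of the top 5% of p65 peaks without a control PDX1 peak, 34.0% (31.3 to 36.7%, 401 of 1181) had an IL-1β PDX1 peak, below the share set for mixed p65 DNA. The 780 that had none, with a median of 91.3 tags, limit a mixture to 3.90%. At 12.5 tags, the median of the 3578 such p65 peaks of any strength that had one, this gives 0.488 tags where 3.56 are needed. That argues against mixing at p65 peaks of median strength. At the strongest p65 peaks the same mixture could reach the tags needed, so mixing stays open there. Without bins, IL-1β-only peaks lay at p65 peaks less often than peaks in both lists, 22.5% against 30.2%. Within 4 bins of tag count the order was the reverse, with IL-1β-only peaks higher by 9.99 points (8.82 to 11.2). The difference was 10.5 points (9.27 to 11.7) when peaks within 500 bp counted as shared. The input shared by both IL-1β lists could raise the share of IL-1β-only PDX1 peaks at p65 peaks. Its test compared IL-1β-only with control-only peaks without bins, so it does not address the difference within bins. With the p65 list of the other genotype, IL-1β-only peaks exceeded control-only ones by 8.74 points in wild-type cells (8.15 to 9.34, 12.0% against 3.25%). In the knockout the excess was 15.6 points (13.3 to 17.8, 43.1% against 27.5%), and the ratio is below the 2 asked for to set the input aside. Those p65 lists also differed in length, with 31389 peaks in wild-type cells and 16162 in the knockout. PDX1 recovery at p65 sites under IL-1β would give such values, while mixed p65 DNA at the strongest p65 peaks, the shared input, opened chromatin, cross-linking through p65 and variation between replicates stay open.

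Wild-type p65 control peaks lay at PDX1 control peaks in 55.4% of cases. Background at strongly recovered PDX1 sites may account for some of them, as the PDX1 peaks concerned had a median percentile of 91.9 in their list. Control p65 peaks not found with IL-1β lay at PDX1 peaks less often than those found, 44.9% against 65.8%, a difference of −20.9 points (−24.3 to −17.5), which under the condition written beforehand would count against background. That condition was judged unsuitable after the result was seen, because background fixed to a PDX1 site would recur in the IL-1β p65 library, and so background stays open together with p65 binding at these sites.

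SIN3A peaks at PDX1 peaks were missing with Pdx1 siRNA in 49.7% of cases (445 of 896) and those elsewhere in 24.8%, with Slc2a2 among the genes left without a SIN3A peak. A need for PDX1 could produce this, but within 4 bins of SIN3A tag count the difference was 3.22 points (0.0920 to 6.35) with all bins weighted equally, and from the lowest to the highest bin, holding 577, 189, 83 and 47 of the SIN3A peaks at PDX1 peaks, it was 10.2, 4.09, 3.998 and −5.36. Weighted by these numbers it was 7.50 points (4.24 to 10.8), and with peaks within 500 bp counted as shared 6.42 points (4.30 to 8.54) with equal weights and 13.4 (10.2 to 16.5) when weighted. The 5 points asked for lie below the last interval but inside the others, that of the written test included, SIN3A peaks present only with Pdx1 siRNA lay at PDX1 peaks in 14.2% of cases against 12.8% of those missing, and whether SIN3A depends on PDX1 stays open.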
